A study of Xenopus laevis with 12 samples.

How the data were processed

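RNA was sequenced from Xenopus laevis oocytes pooled over stages II and III. Per the labels' protocols, lysate was passed over a size exclusion column, fractions enriched for L-bodies were pooled, and RNA was immunoprecipitated from them with a Staufen antibody, an hnRNPab antibody or IgG before sequencing as 150 bp paired reads. L-bodies are the RNA-protein condensates that carry localized RNAs in the oocyte. Each antibody had 4 libraries, 12 in all. The labels do not say whether the replicates came from separate frogs, so p-values measure the spread between these libraries, which may be technical.

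The count files hold whole-number counts per gene as the authors deposited them, with no normalization. The submitters' processing notes name STAR 2.6.1b, HTSeq 0.9.1 and edgeR without a version. The genome build, the annotation and the strand setting are not given in the sources used here. The authors also deposited 2 tables of genes, 1 for Staufen and 1 for hnRNPab, whose values are log2 fold changes and log2 CPM per the file headers. The same deposited tables hold an F score, a p-value and an adjusted p-value for each gene. Every listed gene had an adjusted p below 0.05 and a log2 fold change of at least 0.85. The ranks and p-values of the tables imply 39419 genes tested by the authors, more than the 37365 genes with at least 1 count in any of the 12 count files.

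Genes in the count files carry numbered identifiers. Names came only from the authors' deposited tables, which pair an identifier with a name for 3964 genes, of which 3904 entered the tests here. The other 16899 tested genes have no name here. Every named gene had therefore been selected by the authors as enriched, and no gene list could hold a member outside their tables. A reference gene table of assembly Xenopus_laevis_v10.1 matched 76.5% of the names and served only to count how many genes of each list exist. No coordinates, transcript lengths, GC contents or motifs were used, because no annotation with the same identifiers was at hand.

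Lines of the count files for reads outside genes, reads shared between genes and reads without a unique alignment stayed out of library sizes and tests. Reads outside annotated exons made up 11.0% to 19.6% of the reads with a single alignment, and reads shared between genes 0.521% to 0.791%. Gene counts per library ran from 14147584 to 22103431, so that a count of 0 allowed up to 3 counts, or 0.136 to 0.212 CPM. Such floors cover counting error only. The .L and .S copies of a gene (homeologs, left by the duplication of the X. laevis genome) were counted apart. Reads from near-identical copies can be misassigned, so differences between homeologs are uncertain, as are those of overlapping and antisense genes.

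Counts were analysed with edgeR 4.0.16 in R 4.3.3, with TMM normalization, the default filterByExpr filter (20803 of 51061 genes), a fit over all 12 libraries with the group as the only term, the quasi-likelihood F test and Benjamini-Hochberg adjustment at 0.05. A fold change over a threshold of 2 was tested with glmTreat. Gene lists were tested with camera in limma 3.58.1 with a preset inter-gene correlation of 0.01, for the 11 of the 20 lists with at least 3 tested members. The lists covered vegetally localized maternal mRNAs, germ plasm and germ cell factors, animally enriched maternal mRNAs, transport RNP and L-body proteins, mRNA storage, deadenylation and decapping factors, oocyte maturation and cell cycle, cytosolic ribosomal proteins, translation factors, mitochondrially encoded transcripts, nuclear-encoded respiratory chain subunits, egg coat glycoproteins, secretory pathway and ER folding, cytoskeleton and motor proteins, the Wnt pathway, the TGF-beta, nodal and BMP pathway, hnRNPs and splicing factors, follicle and theca cell, stromal and endothelial cell and blood cell markers, and commonly used reference transcripts. Camera p-values against all tested genes are given for Staufen against IgG only. In the other comparisons most genes listed in a single deposited table moved in the direction that goes with that table, and in Staufen against IgG fewer did. With the replicate number as a block, however, 1025 of the 1482 tested genes in the hnRNPab table alone were lower in Staufen against IgG. Lists in the deposited tables were compared with Fisher's exact test over the genes listed in a single table.

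Genes named in the text were chosen by rule, and values of some genes that it covers are not reported here. For each comparison these were the 8 largest rises and 5 largest falls among genes past the threshold with a name that is not a placeholder, a mean of at least 5 CPM and no overlap between the groups, the antibody targets, up to 4 passing members of each list, and every measured vegetally localized or reference transcript. The design, the lists, this rule and the alternatives were fixed before the data were examined. Counting homeologs once in the Fisher tests and the comparison of the deposited tables with the labelled libraries were added after the data were seen.

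Libraries of the same replicate number deviated together from their group means, with correlations of 0.783 to 0.875 between groups. Libraries of different numbers and different groups correlated at -0.508 to -0.059, and all 12 libraries correlated best with their own number. The pairing comes from the data together with the numbers in the sample titles, and values with the replicate number as a block are given beside results whose call it changes or whose count it moves by over 1.5 times, and beside some other counts. No libraries of a group agreed within sampling noise, since chi-square per degree of freedom was at least 14.4.

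The fits were tested on simulated counts with real means, depths, replicate effects and dispersions and 200 changed genes. Without the block, 44.0% of 2-fold changes were recovered for Staufen against IgG, 42.0% for hnRNPab against IgG and 45.0% for Staufen against hnRNPab. With it, the shares were 89.0%, 93.0% and 87.0%. For 1.5-fold changes the shares were 16.0%, 8.00% and 13.0% without the block and 76.0%, 76.0% and 77.0% with it. False calls made up 0% of calls without the block in all 3 comparisons. With it they made up 8.3%, 7.1% and 3.5%, above the nominal rate in the comparisons with IgG, but each share comes from a single simulated set. The counts were drawn with the replicate effects and dispersions of the blocked fit, which favours that fit. Only 200 genes were changed, where the labelled comparisons called 1618, 7005 and 6837, so these shares do not carry over to the real comparisons.

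The alternatives were RLE and upper-quartile factors, library size alone, no filter, a stricter filter of 2 CPM in 4 libraries, DESeq2 1.42.0, a fit on 2 groups only, the replicate block, the 2-fold test, summed homeologs and leaving out each library.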

Results

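The data comprised counts per gene for 12 libraries of RNA immunoprecipitated from L-body fractions of X. laevis oocytes, 4 each with Staufen antibody, hnRNPab antibody and IgG. Staufen and hnRNPab are RNA-binding proteins of vegetal RNA transport, and IgG served as the control. Summed over genes, the counts were 19270144, 19179780, 17433273 and 22103431 in the libraries labelled IgG, 18678540, 14147584, 15165718 and 17694983 in those labelled Staufen, and 18272830, 17635063, 17832828 and 19202568 in those labelled hnRNPab, in the order of replicates 1 to 4. Reads outside annotated exons made up 18.4% ± 1.16 (SD, n = 4) of singly aligned reads in the libraries labelled IgG, 14.3% ± 0.607 (SD, n = 4) in those labelled Staufen and 12% ± 0.872 (SD, n = 4) in those labelled hnRNPab. These ranges did not overlap, and each difference had p = 0.0286 in a two-sided exact permutation test, the smallest value that 4 against 4 can give (adjusted p = 0.0536 over 15 depth comparisons). The test ignored the pairing of libraries by replicate number. Genes detected at equal depth differed from IgG with the same p (26211 to 26763 for IgG, 25579 to 25857 for Staufen, 25185 to 25637 for hnRNPab). So did the share of the top 100 genes for hnRNPab (8.591% to 11.326% against 7.566% to 8.009%).

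The antibody targets were examined first. Only stau1.S (gene20), a Staufen homeolog, has a name here. The stau2 and hnrnpab genes could not be identified, and may be among the tested genes without a name. Immunoprecipitation selects bound RNA rather than the target's own mRNA, so this gene does not check the labels as a knockout would. Its level was 28.5 ± 4.83 CPM (SD, n = 4) in the libraries labelled IgG, 57.4 ± 8.47 CPM (SD, n = 4) in those labelled Staufen and 51.9 ± 6.72 CPM (SD, n = 4) in those labelled hnRNPab. It was higher in the libraries labelled Staufen than in those labelled IgG by 1.01 on the log2 scale (SE 0.148, edgeR adjusted p = 0.00147) and in those labelled hnRNPab by 0.87 (SE 0.148, adjusted p = 0.000644). The libraries labelled Staufen differed from those labelled hnRNPab by 0.14 (SE 0.146, adjusted p = 0.515).

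The labels and the authors' deposited tables did not match. For a gene listed in both of the authors' deposited tables, subtracting the hnRNPab fold change from the Staufen fold change removes their shared control and leaves Staufen against hnRNPab. Over the 448 such genes tested here, this difference followed the libraries labelled hnRNPab minus the libraries labelled IgG, with r = 0.999998 across genes, a slope of 0.9998 and a median gap of 0.0148 on the log2 scale. Its r with the libraries labelled Staufen minus those labelled hnRNPab was -0.719. Genes are not independent replicates, and these correlations describe the 2 sets of values. Of the 2457 genes in the authors' deposited Staufen table, 171 were called higher and 101 lower in the libraries labelled Staufen against IgG (677 and 519 with the replicate block). Of the 1965 genes in the authors' deposited hnRNPab table, 69 were called higher and 1287 lower in the libraries labelled hnRNPab against IgG (148 and 1579 with the block). All directions below are therefore given for libraries as labelled, without assuming that a label names the antibody used.

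**Figure D1:**
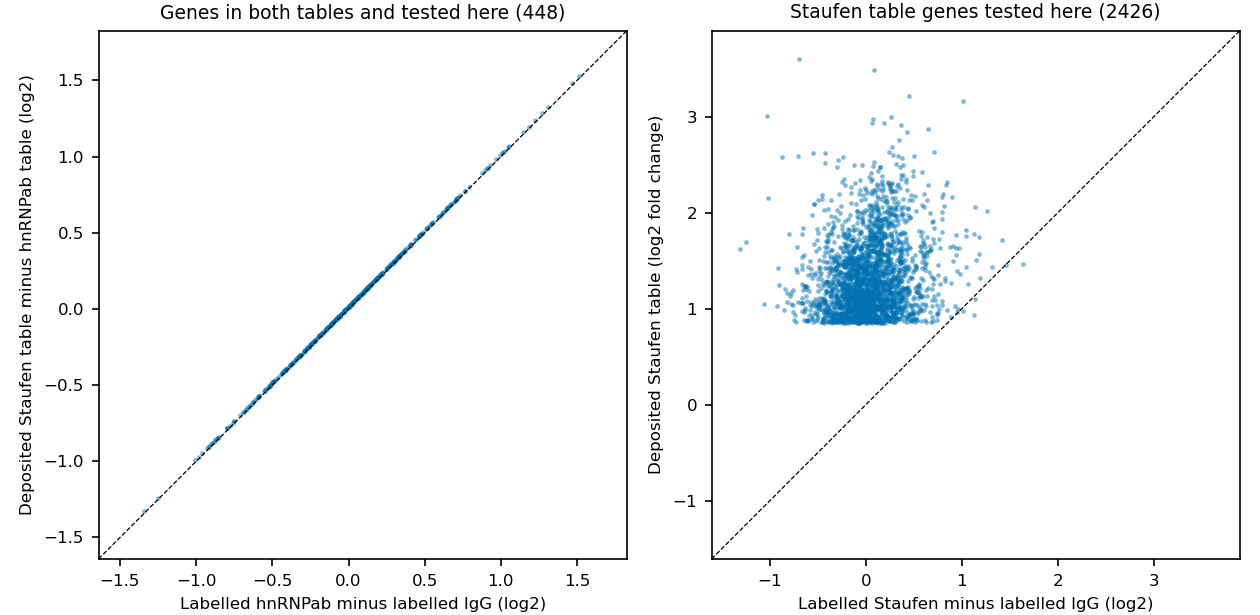
Each point is a gene, and the dashed line marks equal values. Left, the difference of the 2 deposited tables against labelled hnRNPab minus labelled IgG (log2), where 448 genes lie along the line; right, the deposited Staufen table against labelled Staufen minus labelled IgG (log2), where 2426 genes do not follow it.

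The deposited tables themselves describe which transcripts the authors found enriched over their control. They are called by their deposited names, without assuming that a name is the antibody used. In the authors' deposited Staufen table, 2003 genes were listed alone, 1511 were listed in the hnRNPab table alone and 454 were in both. Genes of oocyte maturation and the cell cycle were mostly in the Staufen table, with 18 in the Staufen table alone, 1 in the hnRNPab table alone and 1 in both (Fisher's exact test, adjusted p = 0.00674 over 11 lists). With the homeologs of a gene counted once, 10 symbols against 1 gave adjusted p = 0.238 in the same test (0.0291 unadjusted). With these fewer units, the difference did not pass at the level of symbols. The authors' deposited Staufen table gave log2 fold changes of 2.63 for cdc6.L, a replication licensing factor, 2.48 for cdc25a.S, a phosphatase that activates cyclin-dependent kinases, and 1.53 for fbxo5.S, an inhibitor of the anaphase-promoting complex. The member in the hnRNPab table alone was mos.L, the kinase that drives oocyte maturation, with 1.01 in the authors' deposited table.

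All 4 listed vegetally localized transcripts were in the authors' deposited Staufen table and none in the hnRNPab table (adjusted p = 0.306, Fisher's exact test). They were wnt11b.L, a Wnt ligand (1.15 in the authors' deposited table), bicc1.S and bicc1.L, which encode an RNA-binding protein (1.11 and 0.96), and vegt.S, a T-box transcription factor of the vegetal hemisphere (0.89). They made up 4 of the 33 genes of that list in the reference table. All 8 listed animally enriched transcripts were also in the authors' deposited Staufen table alone (adjusted p = 0.0671), with log2 fold changes of 2.22 for sox3.S and 2.11 for foxi2.S, both transcription factors. Neither list passed the test of a difference between the tables.

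Among the other lists, the Wnt pathway had 19 genes in the Staufen table alone, 5 in the hnRNPab table alone and 3 in both (adjusted p = 0.134, Fisher's exact test). For the TGF-beta, nodal and BMP pathway these counts were 15, 7 and 5 (adjusted p = 0.534), for hnRNPs and splicing factors 8, 2 and 0 (0.372), for cytoskeleton and motor proteins 2, 6 and 0 (0.226), for transport RNP and L-body proteins 6, 6 and 0 (0.944), for mRNA storage, deadenylation and decapping factors 5, 4 and 3 (1.00), for secretory pathway and ER folding 3, 2 and 0 (1.00), and for reference transcripts 3, 0 and 0 (0.415). In all, 6.75% of reference genes were named in either of the authors' deposited tables, and no test was run for lists with fewer than 3 named genes. The authors' deposited tables named 1 of 134 ribosomal protein genes (rps26.L, hnRNPab), 2 of 79 translation factor genes (eif4a1.L and eif4e3.S, Staufen), 0 of 127 respiratory chain genes, 0 of 13 mitochondrially encoded genes and 0 of 8 egg coat genes. Of markers of other cell types, 1 of 25 for follicle and theca (foxo1.L, hnRNPab), 1 of 27 for blood (slc4a1.L, Staufen) and 0 of 31 for stroma and endothelium were named, as was 1 of 22 germ plasm genes (mael.L, Staufen).

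**Figure D2:**
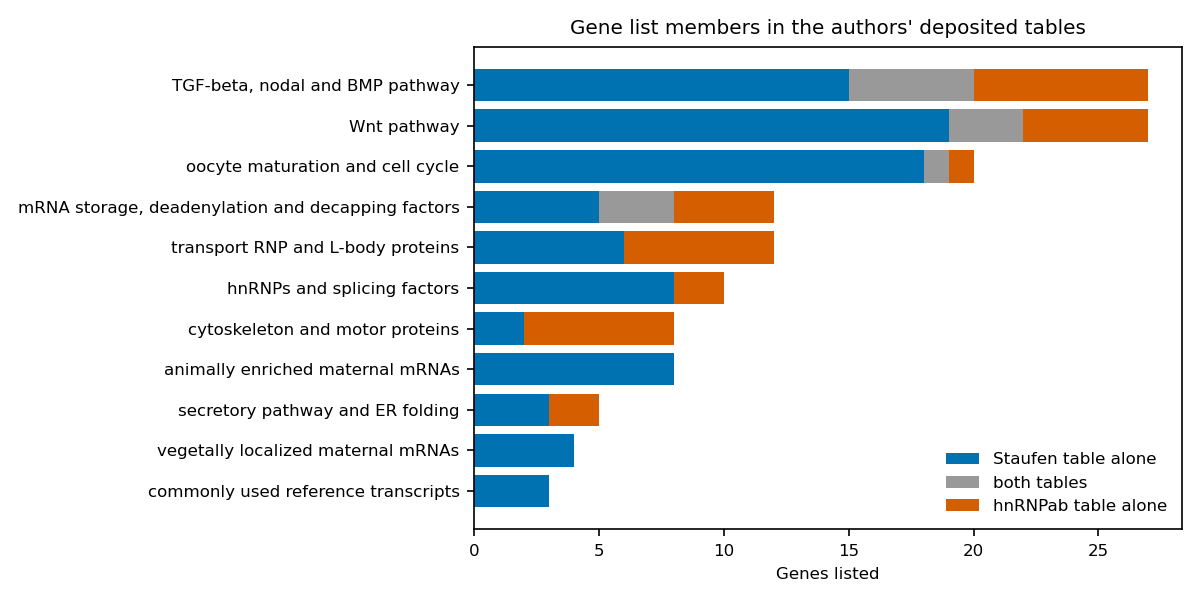
Bars show how many genes of each fixed list with at least 3 listed members the authors' deposited tables contain, in the Staufen table alone, in both or in the hnRNPab table alone. The oocyte maturation and cell cycle list has 18 genes in the Staufen table alone and 1 in the hnRNPab table alone.

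By its labels, the comparison of Staufen with IgG was set up to find RNAs recovered with Staufen above background, and it is given here for libraries as labelled. The libraries labelled Staufen held more vezf1.S (gene7337), a zinc finger transcription factor, at 121 ± 29.5 CPM (SD, n = 4) against 39.1 ± 6.16 in the libraries labelled IgG (3.10-fold, log2 SE 0.199, adjusted p = 0.000486). The centriole assembly gene stil.L (gene12998) was at 615 ± 82.3 against 230.3 ± 7.38 CPM (2.67-fold, log2 SE 0.101, adjusted p = 3.57e-05). Other rises were vezf1.L (2.75-fold), rbm7.L, an RNA-binding protein of the nuclear exosome pathway (2.41-fold), dusp11.S, an RNA phosphatase (2.28-fold), and tfap2c.S, an AP-2 transcription factor (2.20-fold). The largest fall among named genes was that of sec62.L (gene2044), a subunit of the ER translocation machinery, at 10.6 ± 2.73 against 31.1 ± 9.40 CPM (log2 -1.55, SE 0.244, adjusted p = 0.00219). It was followed by txndc15.L (-1.54), brf1.L (-1.48), pla2g4a.L, a cytosolic phospholipase (-1.37), and tmtc2.L (-1.34).

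Of the 4 vegetally localized transcripts, 3 rose in the libraries labelled Staufen over IgG, and 4 did when adjusted over the list alone or with the replicate block. They were bicc1.L (log2 0.74, SE 0.177, adjusted p = 0.0231), vegt.S (0.51, SE 0.133, 0.0378) and bicc1.S (0.33, SE 0.078, 0.0224), while wnt11b.L was at 0.44 (SE 0.173, 0.172; 8.5e-08 with the replicate block). The list passed camera (adjusted p = 0.0016; 0.000488 with the replicate block), but adjusted p = 0.217 with an estimated correlation. All 4 are named by the Staufen table, and of tested genes in that table alone 8.1% were higher here and 1.3% lower, against 4.4% and 1.7% of genes in neither table. Of those in the hnRNPab table alone 1.1% were higher and 21.1% lower, so counts of named genes depend on the tables in this comparison too. With the replicate block, 618 of 1978 genes in the Staufen table alone were higher and 278 lower, against 3175 and 2715 of 16895 in neither. In the hnRNPab table alone 92 of 1482 were then higher and 1025 lower. The camera result for this list is therefore not independent of the tables either. In the fit without the replicate block, the only one run with libraries left out, these calls were fragile. With the block, the edgeR adjusted p was 7.27e-08 for vegt.S, 8.97e-06 for bicc1.S and 1.14e-13 for bicc1.L. The call of vegt.S was lost on leaving out any library but IgG 1 and hnRNPab 2 (adjusted p 0.0547 to 0.139), that of bicc1.S without IgG 3, IgG 4, Staufen 2 or Staufen 3 (0.0558 to 0.0741), and that of bicc1.L without IgG 3, IgG 4 or Staufen 2 (0.0618 to 0.0724). In the fits that lost a call, log2 fold changes ran from 0.383 to 0.56 for vegt.S, 0.283 to 0.336 for bicc1.S and 0.607 to 0.735 for bicc1.L. Without IgG 1, wnt11b.L passed (adjusted p = 0.0421). In a fit on the 2 groups alone all 3 calls were lost (0.0553 to 0.0915), and without a filter those of bicc1.S (0.0592) and vegt.S (0.0526).

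The remaining lists did not pass camera against all tested genes in the libraries labelled Staufen against IgG (adjusted p of at least 0.0579, and 0.0906 with the replicate block). Of the 20 cell cycle genes 1 rose (cdk2.L, log2 0.54, adjusted p = 0.0462, lost without any of 9 libraries at 0.0619 to 0.16 and under 4 other settings at 0.0565 to 0.0803) and 1 fell (mos.L, -0.59, adjusted p = 0.00499). With the replicate block 10 rose and 1 fell. Of the 12 transport RNP and L-body genes, 3 rose (stau1.S; caprin1.S, log2 0.63; caprin1.L, 0.47) and 1 fell, with 4 rises and 5 falls under the block. The caprin1.S call was lost without IgG 2, IgG 3, IgG 4 or Staufen 1 (adjusted p 0.0515 to 0.0717), and that of caprin1.L without IgG 2, IgG 4 or Staufen 2 (0.0505 to 0.065). Among mRNA storage and deadenylation genes pan3.S rose (1.92-fold, adjusted p = 0.000393) and cpeb4.S fell (log2 -0.85, 0.000874), with 2 and 4 of 12 under the block. In the Wnt pathway axin2.S (-1.22) and axin1.S (-0.38) fell and 25 did not pass (9 rises and 9 falls with the block), and in the TGF-beta, nodal and BMP pathway foxh1.L rose (1.73-fold) while zfyve16.S (-1.06), zfyve16.L (-0.83) and skil.L (-0.64) fell (6 and 9 with the block). Of the animally enriched list zfand4.L rose (0.54), with 5 rises and 1 fall under the block, and of the secretory list sec62.L fell (1 rise and 2 falls under the block). The median and mean of the secretory list differed in sign (0.04 and -0.40), as did those of the TGF-beta, nodal and BMP list (0.01 and -0.07) and of hnRNPs (0.03 and -0.01). All 8 cytoskeleton genes and all 10 hnRNP and splicing genes did not pass (2 rises and 4 falls, and 1 rise and 2 falls, with the block). The reference transcripts tbp.L (0.52) and tbp.S (0.60), encoding a general transcription factor, rose, whereas hist1h4a.L was at -0.19 (adjusted p = 0.881).

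Adjusted over the list alone, rises and falls were 1 and 1 for the animal list, 3 and 3 for transport RNPs, 1 and 2 for storage factors, 1 and 1 for the cell cycle and 3 and 3 for the TGF-beta, nodal and BMP pathway, with 2 falls in the secretory list, 1 among cytoskeleton genes, 4 in the Wnt pathway and 2 rises among reference transcripts. In all, 925 genes were higher and 693 lower in the libraries labelled Staufen than in those labelled IgG, of 20803 tested with edgeR. With the replicate block 3944 were higher and 4259 lower. Only 2 genes were higher and 0 lower by more than 2-fold in the test against that threshold, where 47 and 27 had an unadjusted p below 0.05. The count of lower genes was 383 without IgG 2, 421 without IgG 3 and 457 without Staufen 4. Among the called genes 188 higher and 413 lower ones had names.

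The comparison of hnRNPab with IgG was likewise set up for RNAs recovered with hnRNPab, although over 448 genes it followed the Staufen minus hnRNPab difference of the authors' deposited tables. The libraries labelled hnRNPab held more arfgap1.S (gene14627), a GTPase-activating protein of Golgi traffic, at 335 ± 72.1 CPM (SD, n = 4) against 34.4 ± 7.52 in the libraries labelled IgG (9.73-fold, log2 SE 0.202, adjusted p = 2.9e-07). The replication factor cdc6.L (gene9532) was at 1148 ± 320 against 145 ± 39.5 CPM (7.90-fold, log2 SE 0.253, adjusted p = 3.17e-06). Other rises were acp2.S, a lysosomal acid phosphatase (7.46-fold), haus3.L, a subunit of the augmin complex of the spindle (7.44-fold), btg3.S, an antiproliferative factor (7.21-fold), and gnai1.S, an inhibitory G protein subunit (6.88-fold). The largest falls among named genes were those of fam208b.S (log2 -2.89), brf1.L (-2.86), rab8a.S, a GTPase of vesicle traffic (-2.69), spint2.L, a serine protease inhibitor (-2.66), and dnajc5.S, a chaperone of secretory vesicles (-2.61). The level of brf1.L (gene13586) was 73.5 ± 8.08 against 533 ± 82.6 CPM (log2 SE 0.141, adjusted p = 6.37e-08).

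In this comparison the direction of a named gene follows the deposited table that names it. Of tested genes in the Staufen table alone 83% were higher in the libraries labelled hnRNPab than in those labelled IgG. Of those in the hnRNPab table alone 82.9% were lower, and of genes in neither 9.9% were higher and 13.8% lower. With the replicate block, 1922 of the 1978 genes in the Staufen table alone were higher and 1442 of the 1482 in the hnRNPab table alone lower. Of the 16895 in neither, 4435 were then higher and 5358 lower. The counts below are therefore not independent evidence of a list's direction, and no list test is given, since one against all genes or against named genes would restate which table lists the members. Of the 20 oocyte maturation and cell cycle genes, 18 rose and 1 fell (median log2 1.85). They included cdc25a.S (6.40-fold), fbxo5.S (4.96-fold) and cdc6.S (4.93-fold). All 8 animally enriched transcripts, each named by the Staufen table, rose, among them sox3.S (5.65-fold), foxi2.S (4.52-fold) and grhl1.S, a Grainyhead-like transcription factor (3.01-fold). The 4 vegetally localized transcripts, named by the same table, also rose, wnt11b.L 2.87-fold, bicc1.S 2.43-fold, vegt.S 2.28-fold and bicc1.L 1.51-fold. The bicc1.L call was lost without IgG 3, IgG 4 or hnRNPab 2 (adjusted p 0.0507 to 0.0614). The reference transcripts tbp.S (5.14-fold), tbp.L (3.35-fold) and hist1h4a.L, a histone gene (1.68-fold, adjusted p = 0.0494), rose too, and the hist1h4a.L call was lost without any of 9 libraries (all but IgG 1, Staufen 1 and hnRNPab 2; 0.0586 to 0.158), with upper-quartile factors (0.0561), library size alone (0.0731) and homeologs summed (0.054). Counts adjusted over the list alone were the same for these 4 lists.

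In the Wnt pathway 17 genes rose, 3 fell and 7 did not pass (19 and 3 adjusted over the list alone, 21 and 4 with the replicate block), with csnk1d.L, a casein kinase (4.12-fold), gsk3a.L, a kinase of the pathway (3.29-fold), and znrf3.L, a ubiquitin ligase acting on Wnt receptors (2.94-fold). In the TGF-beta, nodal and BMP pathway 15 rose, 6 fell and 6 did not pass (15 and 7 adjusted over the list alone, 16 and 9 with the block), led by the activin receptor genes acvr2b.S (5.28-fold) and acvr2b.L (4.14-fold). Of 10 hnRNP and splicing genes, 8 rose and 2 fell, with hnrnpll.L 4.32-fold up and ptbp3.S at log2 -1.34. Of 8 cytoskeleton and motor genes, 5 fell and 1 rose (2 with the replicate block). Among those that fell were dync1li1.L, a dynein subunit (log2 -1.61), and kif5b.L, a kinesin heavy chain (-1.33).

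Transport RNP and L-body genes went both ways in the libraries labelled hnRNPab, with 5 rises, 6 falls and 1 not passing. The RNA-binding protein gene elavl1.S (log2 -1.27) fell, and caprin1.L rose 2.59-fold. mRNA storage and decapping genes had 5 rises, 5 falls and 2 not passing, including dcp1b.L, a decapping factor (2.67-fold), and tob2.L, which recruits deadenylases (log2 -1.38). In the secretory list 3 rose and 2 fell (median log2 0.51, mean -0.15), with sec62.L at -1.89 and kdelr3.L, an ER retention receptor, at 2.38-fold. Of genes from lists too small to test, slc4a1.L, an anion exchanger of red cells, rose 4.36-fold, eif4a1.L, a translation initiation helicase, rose 1.86-fold, and rps26.L, a ribosomal protein, fell (log2 -0.69).

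Adjusted over the list alone, the counts of the hnRNP, cytoskeleton, transport, storage and secretory lists did not change. In all, 3388 genes were higher and 3617 lower in the libraries labelled hnRNPab than in those labelled IgG (6505 and 6937 with the replicate block). By the test against a 2-fold change, 422 were higher and 259 lower.

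The direct comparison set the libraries labelled Staufen against those labelled hnRNPab, and is not taken as the difference between the antibodies. The libraries labelled Staufen held more wac.S (gene4727) than those labelled hnRNPab, at 314 ± 73.1 CPM (SD, n = 4) against 51.2 ± 10.4 (6.13-fold, log2 SE 0.214, adjusted p = 2.68e-06). Further rises were qser1.S (log2 2.58), sfxn5.L, a mitochondrial carrier (5.87-fold), fam168b.S (5.59-fold), and cyp8b1.S, a cytochrome P450 (4.49-fold). The largest falls among named genes were those of arfgap1.S (log2 -3.02), btg3.S (-2.77), cdc6.L (-2.74), haus3.L (-2.72) and mylip.S, a ubiquitin ligase (-2.60). In arfgap1.S (gene14627) the levels were 41.4 ± 7.65 and 335 ± 72.1 CPM (log2 SE 0.200, adjusted p = 6.4e-07).

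Here too direction follows the tables. In the libraries labelled Staufen against hnRNPab, 80.1% of genes in the Staufen table alone were lower and 0.4% higher. Of those in the hnRNPab table alone 55.6% were higher and 0.6% lower. With the replicate block, 1858 of 1978 were lower and 20 higher, and 1195 of 1482 were higher and 55 lower. The counts are therefore again not independent evidence of direction, and no list test is given. Of 20 cell cycle genes 18 were lower and 1 higher (2 with the replicate block), with cdc25a.S at log2 -2.53 and fbxo43.L, an inhibitor of the anaphase-promoting complex, at -2.18. All 8 animally enriched transcripts were lower (sox3.S -2.24). Of the vegetally localized transcripts, wnt11b.L (-1.08), bicc1.S (-0.95) and vegt.S (-0.68) were lower, the call of bicc1.S being lost with homeologs summed (-0.23, adjusted p = 0.245), and bicc1.L was at 0.15 (adjusted p = 0.583; 0.0198 with the replicate block). In the Wnt pathway 20 were lower and 2 higher (22 and 3 with the block; csnk1d.L -2.34), in the TGF-beta, nodal and BMP pathway 17 lower and 3 higher (18 and 6 with the block; acvr2b.S -2.09), and among hnRNPs 8 lower and 2 higher (hnrnpll.L -2.28). All 3 reference transcripts were lower, and the hist1h4a.L call was lost without Staufen 2, Staufen 3, Staufen 4 or hnRNPab 1 (0.0557 to 0.0645).

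Transport RNP genes were 5 higher and 4 lower (6 and 5 with the block), with elavl1.S 2.25-fold and igf2bp3.L, an RNA-binding protein of vegetal transport, 2.14-fold higher. Storage and decapping genes were 4 higher and 6 lower (ddx6.L, an RNA helicase, 2.54-fold higher). Cytoskeleton genes were 3 higher and 1 lower (5 and 2 with the block; dync1li1.L 3.28-fold higher), and secretory genes had 3 lower and 2 not passing (2 higher with the block). Adjusted over the list alone, 6 transport RNP genes were higher and 5 lower, 4 cytoskeleton genes higher and 1 lower, 3 Wnt genes higher and 20 lower, and 3 TGF-beta, nodal and BMP genes higher and 18 lower, with the other lists unchanged. In all, 3436 genes were higher and 3401 lower in the libraries labelled Staufen (6880 and 6551 with the replicate block), and 181 and 313 by the test against a 2-fold change.

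Genes higher than in the libraries labelled IgG were compared between the other labels. The genes stil.L, vezf1.S, rbm7.L, tfap2c.S, foxh1.L, pan3.S and stau1.S rose in the libraries labelled Staufen and in those labelled hnRNPab, and sec62.L, txndc15.L, brf1.L, pla2g4a.L, tmtc2.L and mos.L fell in both. The level of pan3.S, a deadenylase subunit, was 107 ± 7.70 CPM (SD, n = 4) with IgG, 206 ± 24.8 with the Staufen label and 215 ± 24.1 with the hnRNPab label. There were 282 genes raised with both labels, where independent lists of these sizes give 150.6 (1622 and 1233.3 with the replicate block). Simulated unchanged groups against the same IgG libraries gave at most 0 in 20 simulations, a value that holds no real effects and does not measure what shared IgG libraries add to lists with such effects. With different IgG libraries for each label, the 6 ways of halving them gave 104 to 160 genes, against 50.5 to 64.9 for independent lists. The count was 186 without IgG 2 and 177 without IgG 4. For genes lowered with both, the count was 509 against 120.5 (2850 against 1420.2 with the block). In opposite directions, 227 genes were raised with the Staufen label and lowered with the hnRNPab label, against 160.8 for independent lists, and 40 were lowered and raised, against 112.9. The values for independent lists take every tested gene as equally likely to be called. This was not tested, so those values are only a rough guide. Across genes, which are not independent replicates, the fold changes of the 2 comparisons had r = 0.367 and covariance 0.0887, and simulated unchanged groups had 0.477 and 0.0092. With different IgG libraries for each label, covariances ran from -0.0266 to 0.0553. The IgG libraries used for each label then deviate from the mean of all IgG libraries in opposite directions. On average this lowers the covariance by construction, so these values do not show what remains without shared IgG libraries.

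**Figure D3:**
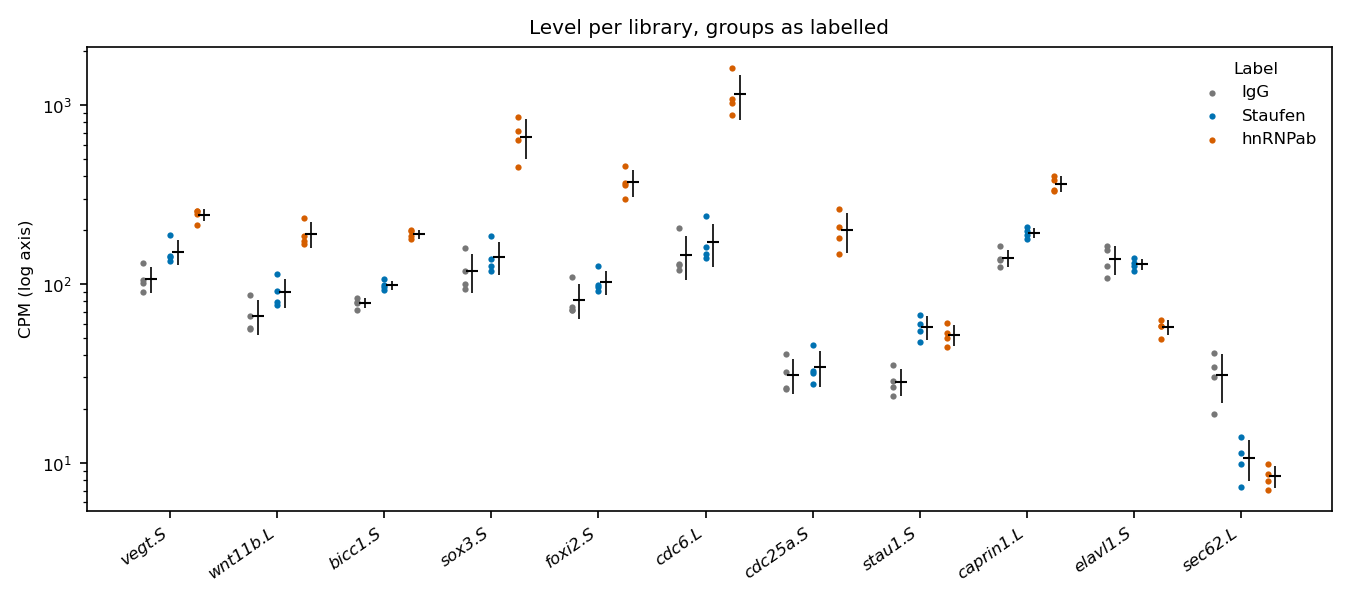
CPM on a log axis for each library, grouped by label, with the mean and SD of 4 libraries for 11 named genes. The cell cycle gene cdc6.L averages 1148 CPM in the libraries labelled hnRNPab and 145 in those labelled IgG.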

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

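Among 324 groups of 4 values, 25 had a library far from the other 3, where chance gives about 1 in 20 groups, or 16.2. Libraries of replicate 1 held 20 of the 25. The groups are not independent, since libraries of the same number deviate together, so the comparison with chance is only a rough guide. No explanation was tested for them.

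In IgG 1, CPM lay above the other IgG libraries for cdc6.L (204 against 120.2 to 129), cdc6.S (219 against 125 to 137), cdc25a.L (232 against 166 to 176), eif4a1.L (275 against 161 to 167), foxi2.S (109 against 71.5 to 74.7) and spcs2.S (75.4 against 50.7 to 54.9). In the same library it lay below them for axin2.S (208 against 246 to 250.1), dync1li1.L (48.9 against 60.7 to 62.3), qser1.S (149 against 294 to 305) and tob2.L (147 against 252 to 256).

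In Staufen 1, CPM lay above the other libraries of that label for caprin1.S (338 against 259 to 271), cdc25a.L (249 against 175 to 181), dcp1b.L (86.0 against 56.1 to 59.9), eif4a1.L (281 against 173 to 185), pabpc4.L (3.42 against 2.50 to 2.63), slc4a1.L (40.5 against 27.0 to 29.3) and vegt.S (187 against 135 to 143), and below them for sfxn5.L (41.0 against 58.8 to 61.1). In hnRNPab 1, cdk2.L was at 176 CPM against 131 to 136 and pla2g4a.L at 21.1 against 34.3 to 36.2. In hnRNPab 2, haus3.L was at 134 against 192 to 200.3. In IgG 4, ccdc50.S was at 7.47 against 6.02 to 6.22, spint2.L at 366 against 293 to 305 and txndc15.L at 124 against 75.7 to 80.7, and in Staufen 4, ccdc50.S was at 11.98 against 8.95 to 9.27.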

How the results depend on the processing

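With the replicate number as a block, calls rose to 3944 higher and 4259 lower for Staufen against IgG, 6505 and 6937 for hnRNPab against IgG and 6880 and 6551 for Staufen against hnRNPab. Genes raised with both rose to 1622, and calls among table genes to 677 (Staufen) and 148 (hnRNPab). Of 152 gene values chosen by rule, the block added the calls of wnt11b.L (Staufen against IgG) and bicc1.L (Staufen against hnRNPab) and changed no other of them. Over all named genes, calls for Staufen against IgG rose from 188 to 768 higher and from 413 to 1544 lower. Against a 2-fold change, edgeR called 2 and 0, 422 and 259, and 181 and 313 genes, 0 raised with both, and 0 and 3 table genes. At an unadjusted p under 0.05 that test had 47 and 27 genes for Staufen against IgG, 5 raised with both and 6 of the Staufen table. A higher bar gives fewer calls by construction. DESeq2, which tested no such bar, gave 1343 higher and 1176 lower genes for Staufen against IgG, 427 raised with both, and 242 and 78 table genes. With no filter 442 genes were lower for Staufen against IgG. Except for the block and the 2-fold test, the cause was not tested.

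Leaving out 1 library gave 628 to 950 higher and 383 to 960 lower genes for Staufen against IgG and 177 to 336 raised with both. The correlation of the table difference with labelled hnRNPab minus IgG ran from 0.977638 to 0.999998. For bicc1.L, Staufen against hnRNPab turned to -0.23 with homeologs summed, where it takes the value of both copies and the call of bicc1.S is lost as well (adjusted p = 0.245), and hist1h4a.L, Staufen against IgG, to 0.081 without IgG 1 (-0.46 to 0.081 over the libraries left out). None of these values passed. Of the 152 values, 131 had no changed call outside the 2-fold test. The other counts for the 3 comparisons and for genes raised with both stayed within 1.5 times of their value under other factors, filters, the 2-group fit and summed homeologs. Counts of table genes were run only for the block, the 2-fold test and DESeq2. The block with a length trend was not run. Depth limits genes of low count, since 3 counts equal 0.136 to 0.212 CPM.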

Other observations

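The tests of the labels and of the share of reads outside exons were chosen after the result was seen; those of homeologs and of other splits before.

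Homeologs tended to be listed together. Of 368 pairs with each copy in a single deposited table, 316 (85.9%) had both copies in the same table, 191 in the Staufen table and 125 in the hnRNPab table, and 52 were in different tables. In a permutation test, 100000 permutations of the tables gave 190.0 pairs on average and at most 228 (permutation p = 1e-05, the smallest they can give), which argues against independent listing. Reads shared between near-identical copies stay open as a candidate explanation, since the 52 split pairs do not decide without sequences. The copies of sox3, cdc6 and cdc25a were together in the Staufen table, and those of elavl1 in the hnRNPab table.

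Principal component 1 (34.3% of variance) ran from -98.59 to -28.33 in the libraries labelled hnRNPab and from -27.62 to 60.57 in the others. It also set replicate 1 apart, which was lowest within each label. Replicate 1 was at -19.43 against 34.34 to 60.57 for IgG and -27.62 against 22.86 to 52 for Staufen. For hnRNPab it was at -98.59 against -43.72 to -28.33. Among genes without a name, gene3891 was higher (log2 1.91, adjusted p = 0.00034) and gene11108 lower (-2.35, adjusted p = 0.0013) in the libraries labelled Staufen against IgG by edgeR.

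The deposited tables and the labelled libraries differ in a way that the labels or the names of the tables may account for. The difference of the tables had r = 0.999998 with labelled hnRNPab minus IgG, a hypothesis being that the libraries labelled hnRNPab are the tables' Staufen arm and those labelled IgG their hnRNPab arm. Exchanged table names would need r near 1 with labelled hnRNPab minus Staufen, which was 0.719. Normalization or filtering would shift all genes alike, but the gap between the Staufen table and labelled Staufen minus IgG had a median absolute deviation of 0.438, and with the libraries labelled Staufen as the tables' control it was 0.476. Over all pairs of labels, the lowest such deviation was 0.438 for the Staufen table and 0.361 for the hnRNPab table. The pair with the lowest deviation was not the one with the highest r. For the Staufen table r was 0.153 with labelled Staufen minus IgG and 0.576 with labelled hnRNPab minus IgG. For the hnRNPab table it was 0.347 with labelled IgG minus Staufen and 0.439 with labelled IgG minus hnRNPab. Over these genes, deviations this large argue against any labelled group, taken whole, as the tables' control. Which libraries were the control stays open, libraries outside these 12 included, since the tables imply more tested genes than the 37365 with a count here. No biological explanation was tested.

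Reads outside exons were a larger share with the IgG label than with Staufen, and larger with Staufen than with hnRNPab, in 4 of 4 replicate numbers. If depth alone set the share, the deeper library was taken to have the larger one in all 12 pairs of the same number. It did in 8. A share need not rise with depth, and the pairs reuse the same libraries, so this count does not decide. The library labelled IgG was deeper than that labelled Staufen in all 4 numbers, so depth and label cannot be told apart there. The libraries labelled Staufen were deeper than those labelled hnRNPab in only 1 number, but had the larger share in all 4. A difference in the RNA recovered stays open, as untested.

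Other splits of the 8 libraries were compared with the labelled one. For Staufen against IgG, 1 of 35 splits gave as many as 1618 genes, the real one (highest other 0), for hnRNPab against IgG 1 of 35 gave 7005 (highest other 0) and for Staufen against hnRNPab 1 of 35 gave 6837 (highest other 0). At an unadjusted p under 0.05 the highest other splits had 3962, 6080 and 5407 genes, against 3974, 8680 and 8588. Only 8 splits part all 4 pairs as the labelled one does, too few for a share under 0.05, and the highest other among them was 0. The others leave paired libraries on the same side. For lists passing camera against all tested genes, 19 of 35 splits gave at least the 1 list of Staufen against IgG (highest other 5), so chance is not excluded there. For the 7 lists of Staufen against hnRNPab 4 of 35 splits gave as many (highest other 7), and for the 8 of hnRNPab against IgG 1 of 35 (highest other 7), but in these comparisons direction follows the table that names a gene, so both counts decide nothing. For genes raised with both, 1 of 60 regroupings gave 282, the real one (highest other 0). The others were drawn at random over the 12 libraries, without regard to replicate numbers. Like the other splits of 8 libraries, which also called 0 genes, they mix the labelled groups, so this count does not exclude chance.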
